A study of Homo sapiens with 6 samples.

How the data were processed

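Total RNA of sorted primary human NK cells was hybridised to 6 whole-transcriptome Affymetrix arrays, 1 colour each. Per the labels' protocols, NK cells were enriched from healthy donors by a CD3-negative, CD56-positive gate, kept for 24 h with K562 cells and 10 ng/ml IL-2, and sorted again as CD3-negative and CD56-positive into a PD-L1-positive and a PD-L1-negative fraction. Biotin-labelled single-stranded cDNA was made from 100 ng RNA with the GeneChip WT PLUS kit, per the labels' protocols. The labels name donors 1, 2 and 3 in each fraction, so the replicates of a fraction were separate people and the fractions of a donor were pairs.

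The authors deposited log2 signal values in 1 table of 138745 probe set rows and 6 columns, and all columns were used. The submitters' processing notes name Affymetrix Expression Console and Transcriptome Analysis Console, and the background correction and normalization are not given in the sources used here. The log scale was read from the values, which ran from 2.20 to 19.93 with sample medians from 4.05 to 4.11, and the table was used as deposited, without another normalization. The number of arrays, 3 per fraction, limits the precision. No genome build was named, so no coordinates are given.

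Probe sets were named through the platform annotation, which lists 37295 of the rows. Of these, 36176 had 1 gene symbol and 1119 had several, and 101450 rows were unnamed here; rows with several symbols named no gene. Symbols were updated with the RefSeq gene table of GRCh38.p14, used for names only, through the Entrez ID for 25516 rows, the symbol for 9899 and a synonym for 623, and 138 kept the symbol of the array. The 2995 control rows entered no gene test, and 413 rows of XIST and Y-linked genes were left out of all tests. Where a gene had several rows (1668 of 33090 genes), the row with the highest mean over all samples was kept. Genes were tested when that mean was at or above 4.06, the median of the row means, which left 21464.

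The fractions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), over all 6 samples, without the donor, 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. CD274 was taken from the same fit without the brightness filter. Gene lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 28 of 30 lists with at least 5 tested members. The lists were cytotoxic granule and death ligand, NK activating receptor and adaptor, inhibitory receptor and checkpoint, activation and costimulation, cytokine and chemokine, NF-kB, PI3K-AKT-mTOR, immediate early and AP-1, IL-2 and STAT5 response, type I interferon, interferon-gamma, glycolysis, cholesterol synthesis, oxidative phosphorylation, amino acid starvation and unfolded protein response, heat shock, p53 and apoptosis, S phase, G2 and mitosis, CD56-bright, CD56-dim, NK transcription factor, homing and adhesion, and ribosomal protein genes, and markers of K562 and erythroid cells, monocytes, dendritic cells, T cells, B cells and platelets. They held 494 genes, of which 396 were tested, 47 were below the brightness filter, 21 lay on rows with several genes and 30 had no named row, and 14 genes were in more than 1 list. Near-identical gene copies, such as HBA1 and HBA2, XCL1 and XCL2, or HSPD1 and HSPE1 with their pseudogenes, can share probes, and their values are uncertain for that reason.

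The tests, lists, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule named CD274, the 10 called genes with the largest rise and the 10 with the largest fall among those with the same direction in all 3 donors, and up to 4 members of each list with the lowest p. It was not kept in full for the marker lists of other cell types and the CD56-bright, G2 and mitosis, and ribosomal protein lists. From these, HBA1, BANK1, CCR7, XCL1, AURKA and CCNB1 were kept by a choice made after the values were seen. Other genes are named as chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.

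The fit was tested on simulated data with 21464 genes, 200 of them changed, in 20 simulations. It recovered 0.0746% of genes changed by 0.5 on the log2 scale, 4.78% of those changed by 1 and 65.2% of those changed by 2, with 3.45% false calls. A planted list was found in 20 of 20 simulations, and an unchanged list passed in 1, both by the list test's p without adjustment over lists. These counts therefore do not describe the adjusted list calls made below. The planted change had 1 size, so the count does not show how small a list shift can be found. Simulated genes were independent, without a donor effect shared by the fractions, so the list results do not test the preset correlation. Far more genes were called in the data (3662) than were changed in the simulation, so the recovery rates need not hold there.

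Samples of the same donor deviated together from their group means, with correlations across genes of 0.19, 0.206 and 0.206 in the 3 donors. Genes are not independent replicates. Samples of different donors did not deviate together (highest -0.0612). Deviations within a group cancel out, so these negative values follow from the positive ones within donors and are no separate evidence. The donor numbers of the titles were therefore used as pairs in an alternative fit with the donor as a replicate block. No 2 arrays held the same values. Other alternatives were a random donor block, leaving out each array and each donor, quantile normalization, median centring, eBayes with trend and robust, the mean of a gene's rows, no filter or a filter at the 75th percentile, all rows tested, and other thresholds. Centring on the positive control rows, protein-coding genes alone, the estimated correlation with the replicate block, and 5 added gene lists were chosen after the data were seen. Background was taken as 7.02, the mean over arrays of the 95th percentile of the 612 negative control rows.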

Results

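Gene expression was measured on 6 arrays, from PD-L1-positive and PD-L1-negative natural killer (NK) cells of 3 healthy donors. NK cells are lymphocytes that kill tumour cells without prior priming. Primary NK cells, gated as CD3-negative and CD56-positive, were cultured for 24 h with K562, a myeloid leukemia line that NK cells recognise as a target, in 10 ng/ml IL-2. Each donor's cells were then sorted on the same gate plus surface PD-L1, a ligand of the checkpoint receptor PD-1, so each fraction had n = 3 arrays. Sample medians lay between 4.05 and 4.11 on the log2 scale, and the number of arrays limits the precision. Differences below are PD-L1-positive minus PD-L1-negative on the log2 scale, and levels are means ± SD of 3 donors. The SE is that of the fit without the donor, which ignores that the fractions of a donor were pairs. With the donor as a replicate block, the SE went from 1.00 to 0.34 for TNFSF4 and from 0.23 to 0.26 for TCP11L2.

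CD274, the gene of the sort marker PD-L1, was the check of the labels and is no finding between the fractions. Its level was 14.9 ± 0.188 in the PD-L1-positive and 9.32 ± 0.551 in the PD-L1-negative fraction, a log2 difference of 5.55 (SE 0.28) or 47.0-fold. The limma adjusted p over all named genes was 0.000175, and the exact permutation p was 0.1, the smallest that 3 against 3 samples allow. The difference was 4.81, 6.12 and 5.74 in donors 1, 2 and 3. CD274 was also detected in the PD-L1-negative fraction, above 7.02, the mean 95th percentile of the negative control probes. The sort purity was at least 96%, so this signal does not show that PD-L1-negative cells themselves expressed CD274.

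The comparison asked which transcripts differed between NK cells with and without surface PD-L1 after culture with the same target cells. Whether the cells of both fractions had been in contact with K562 to the same extent was not measured. Effects of such contact and of PD-L1 status cannot be told apart here. In the PD-L1-positive fraction, lists of DNA replication, protein folding, mitochondrial respiration, cholesterol synthesis and costimulation genes were called higher, and those of mature CD56-dim NK cells, inhibitory receptors, adhesion and the type I interferon response lower, at the preset correlation of the list test. None of these lists was called with an estimated correlation, and in several most members were not past the test, such as 15 of 21 type I interferon genes. Of 21464 genes tested, 3662 (17.1%) passed an adjusted p of 0.05, with 2461 higher and 1201 lower in PD-L1-positive cells. The counts depended on single samples: 1569 were higher and 760 lower without the PD-L1-positive array of donor 3. Without both arrays of that donor they were 785 and 404, and 1881 and 1019 with the donor as a replicate block. Each of the 3662 genes differed in the same direction in all 3 donors. They were selected by a test on these same samples, which favours such genes, so this is no separate support from the donors. The share among all tested genes is not given. At least a 2-fold difference was reached by 1979 of the higher and 903 of the lower genes.

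Among the 10 genes with the largest rise, SRM, which makes the polyamine spermidine, went from 8.55 to 14.6 ± 0.222, a log2 difference of 6.07 (SE 0.24, adjusted p = 1.9e-05). CTPS1, which makes the nucleotide CTP, rose by 5.19 (SE 0.44, adjusted p = 0.000504), and MCM4, a subunit of the replicative helicase, by 4.78 (SE 0.48, adjusted p = 0.000614). TNFSF4, the OX40 ligand, rose by 5.24 (SE 1.00, adjusted p = 0.00679). NETO2 (5.28), RGS16 (4.79), SEMA4A (4.75) and TMEM97 (4.64) rose as well. CCL1, a chemokine, had the largest difference of the called genes, 6.64, but with an SE of 1.96 and an adjusted p of 0.0473. Its PD-L1-positive level was 15.4 and 14.2 in 2 donors and 6.00 in the other, against 5.23 ± 0.297 in the PD-L1-negative fraction.

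Among the 10 genes with the largest fall, YPEL3, a growth-suppressing p53 target, had a log2 difference of -6.18 (SE 0.70, adjusted p = 0.00079), and FCMR, the Fc receptor for IgM, one of -6.16 (SE 0.35, adjusted p = 0.000103). The NK receptors CD160 (-6.03, SE 0.45) and KLRF1 (-5.78, SE 0.54) and the cytotoxic-cell secreted protein FGFBP2 (-5.93, SE 0.76) fell with adjusted p of 0.000392, 0.000524 and 0.00116. The chemokine receptor CXCR4 went from 14.2 to 8.60 ± 1.02, a difference of -5.56 (SE 0.44, adjusted p = 0.00043). MXI1 (-4.92), an antagonist of MYC, CD109 (-4.56), CCNG2 (-4.52) and TCP11L2 (-4.49) completed the group. Several of these genes were at or under the 7.02 background level in one fraction, so their folds are of uncertain size. This applied to CCL1, NETO2, CTPS1, RGS16, MCM4, SEMA4A and TMEM97 in PD-L1-negative cells, and to CD160, FGFBP2, CD109 and TCP11L2 in PD-L1-positive cells.

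**Figure D1:**
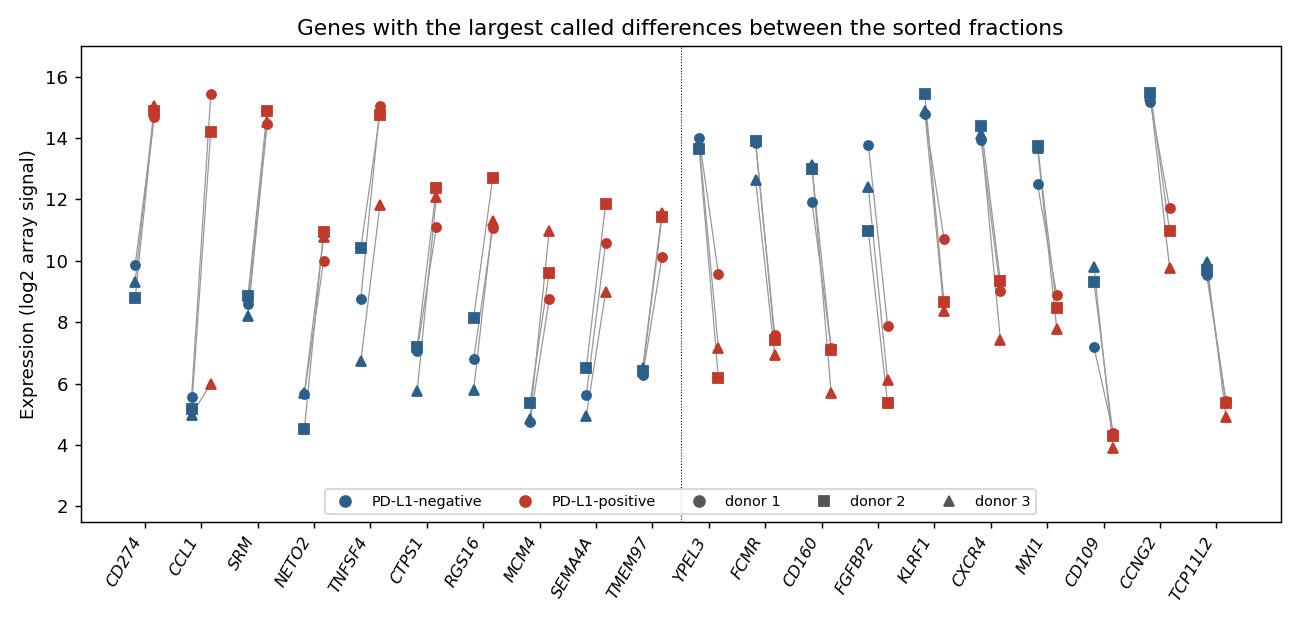
Log2 array signal of the 10 genes with the largest rise and the 10 with the largest fall, 1 point per sample, with shape for the donor, colour for the fraction and a line joining the fractions of a donor. CD274 lay between 14.7 and 15.1 in PD-L1-positive samples, and CCL1 in donor 3 was 6.00 against 15.4 and 14.2 in the other donors.

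The S phase list was called higher at the preset correlation. Of 17 tested S phase genes, 13 rose and none fell (13 when adjusted over the list alone), with a median log2 difference of 2.13 (camera adjusted p = 3.2e-10; adjusted p = 0.348 with an estimated correlation). The median level of the list was 8.76 and 6.17 in the PD-L1-positive and PD-L1-negative fractions, the latter under the background level, so the size of the rise is uncertain. The helicase subunits MCM5 (3.78, SE 0.36) and MCM7 (3.76, SE 0.38) and the replication licensing factor CDC6 (2.23, SE 0.23) were among them. Of 15 tested G2 and mitosis genes, 2 rose, AURKA (1.05) and CCNB1 (1.00, from 5.97 to 6.97, both under the background level), and neither passed when adjusted over the list alone. That list had a median of 0.34 and was not called (adjusted p = 0.16), and its median level was 5.44 and 5.03 in the PD-L1-positive and PD-L1-negative fractions, under the background level. MKI67, chosen after its values were seen, stood at 4.66 and 4.69.

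The heat shock, respiration and cholesterol synthesis lists were also called higher at the preset correlation. Of 7 tested heat shock genes, 5 rose (5 adjusted over the list alone) with a median of 2.33 (adjusted p = 0.000355; adjusted p = 0.284 with an estimated correlation), including the mitochondrial chaperonins HSPD1 (3.30) and HSPE1 (2.56) and the cytosolic chaperones HSPH1 (3.09) and HSP90AB1 (2.33). Of 17 oxidative phosphorylation genes, 10 rose (12 adjusted over the list alone) with a median of 1.17 (adjusted p = 6.2e-06; adjusted p = 0.348 with an estimated correlation). They included cytochrome c (CYCS, 1.77), NDUFA9 (1.84) and the ATP synthase subunits ATP5F1A (2.07) and ATP5F1B (1.41). Of 12 cholesterol synthesis genes, 5 rose (8 adjusted over the list alone) with a median of 0.98 (adjusted p = 0.00194; adjusted p = 0.284 with an estimated correlation). DHCR7 (2.67), SQLE (1.63), FDPS (1.48) and HMGCS1 (1.11) had the lowest p.

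The glycolysis list was called lower at the preset correlation. Of 18 tested, 6 fell, 12 were not past the test and none rose (6 lower and 1 higher adjusted over the list alone), with a median of -0.24 (adjusted p = 0.00586; adjusted p = 0.284 with an estimated correlation). The enzymes ALDOC (-2.21), PFKL (-1.24), PFKFB3 (-1.20) and GPI (-1.10) had the lowest p. GAPDH (19.86 and 19.87 in the PD-L1-positive and PD-L1-negative fractions) and LDHA (19.80 and 19.88) were chosen after their values were seen. Both were at the top of the scale, where a difference could not be resolved, so the list result does not cover them. Of 16 genes of amino acid starvation and the unfolded protein response, 4 rose (5 higher and 1 lower adjusted over the list alone), namely the serine synthesis enzyme PSAT1 (3.17), the amino acid transporter SLC7A5 (2.08), ASNS (1.69) and CHAC1 (1.67), and the list was not called (median 0.35, adjusted p = 0.119). None of 9 tested ribosomal protein genes was called (0 adjusted over the list alone; median 0.38, adjusted p = 0.316).

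The costimulation and NF-kB lists were called higher at the preset correlation. Of 11 activation and costimulation genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 1.35 (adjusted p = 0.0127; adjusted p = 0.284 with an estimated correlation). CD83 (4.15, SE 0.40), the TNF receptor family members TNFRSF9 (2.19) and TNFRSF18 (2.32), and the IL-2 receptor chain IL2RA (1.48) rose, TNFRSF9 to 19.8, near the top of the scale, whereas the early activation marker CD69 fell (-1.46; chosen after its values were seen). Of 20 NF-kB targets and regulators, 8 rose and 2 fell (9 and 3 adjusted over the list alone), with a median of 0.61 (adjusted p = 0.0127; adjusted p = 0.348 with an estimated correlation). SOD2 (2.89), the survival gene BCL2L1 (1.63), the adhesion molecule ICAM1 (1.60) and BIRC3 (1.31) rose.

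Of 16 IL-2 and STAT5 response genes, 6 rose (9 higher and 1 lower adjusted over the list alone), with a median of 0.89 (adjusted p = 0.045; adjusted p = 0.348 with an estimated correlation). IL2RA, the cyclin CCND2 (1.97), STAT5A (1.38) and the cytokine OSM (1.99) had the lowest p, and CCND2 at 19.6 in PD-L1-positive cells was near the top of the scale. Of 17 interferon-gamma response genes, 5 rose (6 higher and 1 lower adjusted over the list alone), with a median of 0.64 (adjusted p = 0.045; adjusted p = 0.562 with an estimated correlation), including WARS1 (1.52), JAK2 (1.43), the transcription factor IRF8 (1.27) and ICAM1. The type I interferon response list was called lower at the preset correlation alone. Of 21 tested, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of -0.81 (adjusted p = 0.000606; adjusted p = 0.586 with an estimated correlation). The median was -0.276 without the PD-L1-positive array of donor 2, and fry did not call this list (adjusted p = 0.215). HERC5 (-3.21), IFIT1 (-2.41) and OAS1 (-1.47) fell, and IFI27 (1.68) rose from 4.44 to 6.12, both under the background level.

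Cytokine genes moved in both directions. Of 20 tested, 4 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of 0.05 and no call for the list (adjusted p = 0.849). Lymphotoxin alpha (LTA, 3.89, SE 0.32) and TNF (3.68, SE 0.41) rose, and CCL5 (-1.46) and TNFSF14 (-1.91) fell. IFNG, chosen after its values were seen, read 19.91 and 19.87 in the PD-L1-positive and PD-L1-negative fractions, at the top of the scale, where a difference could not be resolved. Of 20 immediate early and AP-1 genes, 5 rose and 3 fell (5 and 5 adjusted over the list alone), with a median of -0.04, a mean of 0.08 and no call (adjusted p = 0.849). MYC (4.26, SE 0.47), FOSL1 (3.63) and the phosphatase gene DUSP4 (3.20) rose, and FOSL2 (-2.97) fell. Of 18 PI3K-AKT-mTOR components, 1 rose and 4 fell (1 and 4 adjusted over the list alone), with a median of 0.11, a mean of -0.09 and no call (adjusted p = 0.549). RPTOR (1.85), a subunit of mTOR complex 1, rose, and FOXO3 (-2.25), the inhibitory phosphatase gene INPP5D (-2.00) and RICTOR (-0.96) fell. Of 11 p53 and apoptosis genes, 2 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.71 and no call (adjusted p = 0.416). BAX (0.87) and ZMAT3 (0.94) rose, and SESN1 (-3.36) and CASP8 (-1.32) fell.

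Lists of NK cell receptor genes were called lower at the preset correlation, with most members not past the test. Of 13 inhibitory receptors and checkpoints, 5 fell and none rose (8 lower and 2 higher adjusted over the list alone), with a median of -0.83 (adjusted p = 0.00279; adjusted p = 0.284 with an estimated correlation). KLRG1 (-3.18), KLRB1 (-2.48), CD96 (-1.42) and LAIR1 (-1.18) had the lowest p. Of 17 activating receptors and adaptors, 6 fell and 2 rose (7 and 3 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.045; adjusted p = 0.589 with an estimated correlation). The median was -0.0128 without the PD-L1-positive array of donor 2 (adjusted p = 0.139) and -0.119 without the PD-L1-negative array of donor 1 (adjusted p = 0.128), so the list call was fragile. KLRF1, CD160 and the signalling chain CD247 (-1.67) fell, and the adhesion receptor CD226 (1.93) and NCR3 (2.05; chosen after its values were seen) rose. Of 19 cytotoxic granule and death ligand genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.25 and no call (adjusted p = 0.387). The Fas ligand gene FASLG (1.84), the granzyme GZMH (1.77), the granzyme inhibitor SERPINB9 (1.71) and STX11 (1.43) rose.

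The list of CD56-dim NK cells, the mature cytotoxic subset, was called lower at the preset correlation. Of 11 tested, 4 fell, 7 were not past the test and none rose (4 adjusted over the list alone), with a median of -0.92 (adjusted p = 0.000219; adjusted p = 0.348 with an estimated correlation). The chemokine receptor CX3CR1 (-4.04, SE 0.57), S1PR5 (-3.16, SE 0.31), FGFBP2 and CXCR2 (-1.19) fell, CXCR2 from 6.51 to 5.32, both under the background level. FCGR3A, chosen after its values were seen, had a difference of -0.92 (SE 0.67, adjusted p = 0.429) and was called lower with the donor as a replicate block (SE 0.26, adjusted p = 0.0301). Over all settings the difference of FCGR3A ran from -1.74 to -0.325. Of 9 CD56-bright markers, only CCR7 (3.96, SE 0.99, adjusted p = 0.0239) was called (1 adjusted over the list alone), with a list median of -0.16, a mean of 0.14 and no call (adjusted p = 0.761). XCL1 of this list had a difference of -2.72 (SE 1.15, adjusted p = 0.155; 0.0026 with the donor as a replicate block), and -1.14 without the PD-L1-positive array of donor 3. NCAM1, which codes for CD56 and was chosen after its values were seen, was lower, at 14.3 ± 0.722 against 16.3 ± 0.221 (log2 difference -2.01, SE 0.34, adjusted p = 0.00417). With the mean of all its rows, NCAM1 was at -1.27 and not called (adjusted p = 0.0996).

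Of 14 homing and adhesion genes, 6 fell and none rose (6 adjusted over the list alone), with a median of -0.42 (adjusted p = 0.00279; adjusted p = 0.348 with an estimated correlation). CXCR4, the selectin ligand SELPLG (-2.49), and the integrin chains ITGAX (-2.43) and ITGB2 (-1.42) had the lowest p. Of 16 NK transcription factors, 1 rose and 3 fell (2 and 6 adjusted over the list alone), with a median of -0.13 and no call (adjusted p = 0.119), although it was called lower with quantile normalization (adjusted p = 0.0228). ZBTB16 (-3.77), KLF2 (-2.73) and GATA3 (-1.16) fell, and TBX21 (0.95) rose.

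**Figure D2:**
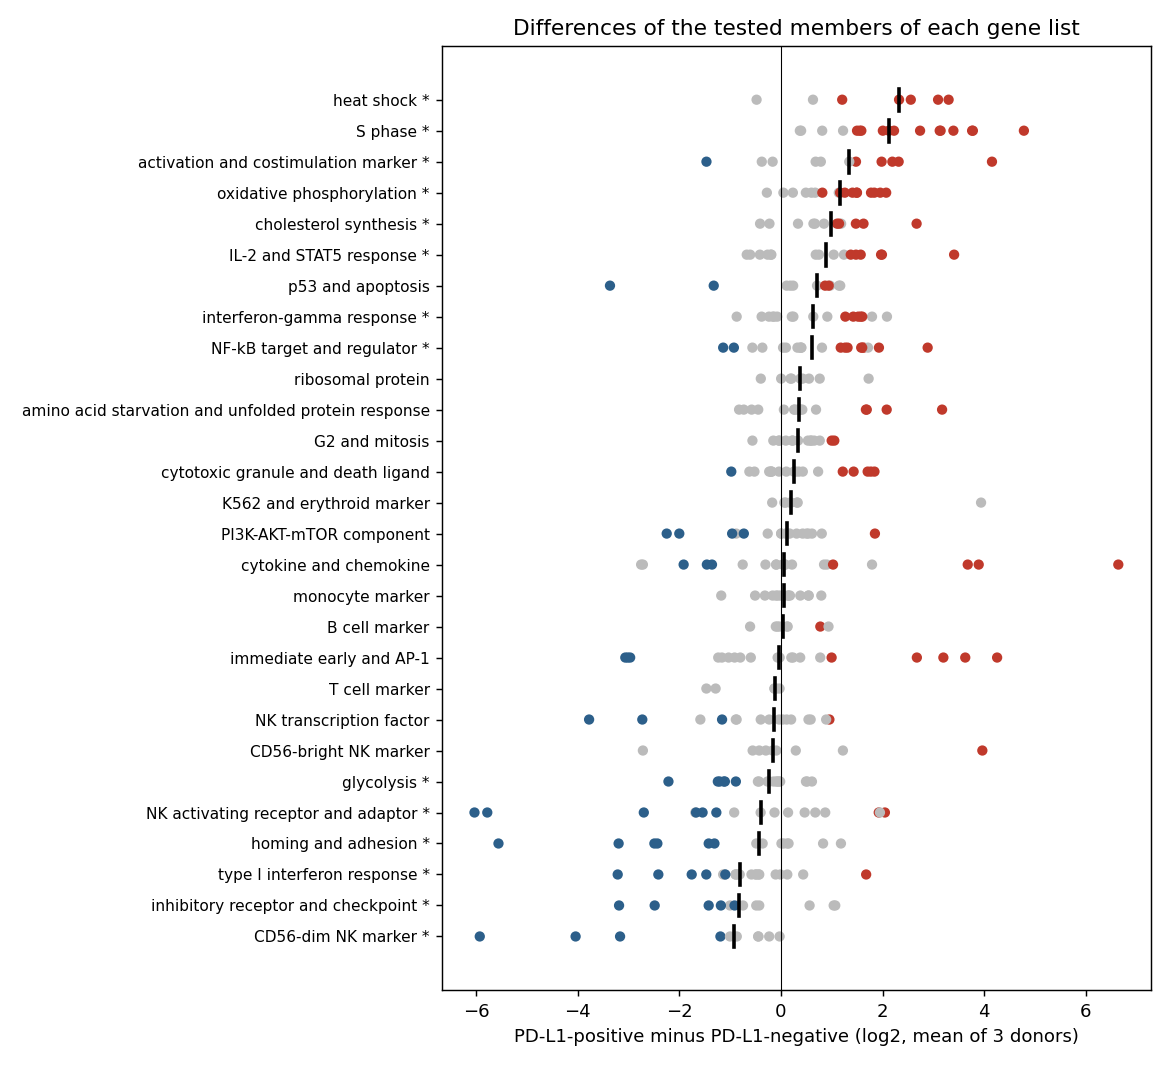
Log2 differences of the tested members of 28 gene lists, mean of 3 donors, 1 point per gene, with red and blue for genes called higher and lower, grey for the rest, a black bar for the list median and an asterisk for lists called by camera with its preset correlation. Medians ran from -0.92 for CD56-dim markers to 2.33 for heat shock genes.

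Few markers of cell types that the sort could have carried over were called. None of 8 tested K562 and erythroid markers was called (0 adjusted over the list alone; median 0.19, adjusted p = 0.549), and of 15 measured markers HBA1 alone was above the background level. HBA1, an alpha globin gene, had a difference of 3.94 (SE 1.59, adjusted p = 0.136; 0.00428 with the donor as a replicate block), and 1.79 without the PD-L1-positive array of donor 1. None of 16 monocyte markers was called (0 adjusted over the list alone; median 0.05, direction of the test downward, adjusted p = 0.908), nor of 6 T cell markers (0 adjusted over the list alone; median -0.13, adjusted p = 0.364). Of 8 B cell markers, 1 was called, BANK1 (0.78, from 5.53 to 6.31, both under the background level; 0 adjusted over the list alone), with a list median of 0.05 (adjusted p = 0.849). None of 4 tested dendritic cell markers (median 0.09) and of 3 platelet markers (median 0.06) was called, over all genes or adjusted over the list alone, and these lists were too short for a test. CD68, LAMP3, IL3RA, CD3E, CD6 and CD79B of these lists were above the background level in both fractions and AIF1 in the PD-L1-positive fraction. Of these, IL3RA (2.00, adjusted p = 0.115; 0.00247 with the donor as a replicate block) and AIF1 (0.80, adjusted p = 0.0832; 0.0331 with that block) were higher in all 3 donors, and LAMP3 differed by -0.08. In all, 1 T cell marker was also in another list.

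**Figure D3:**
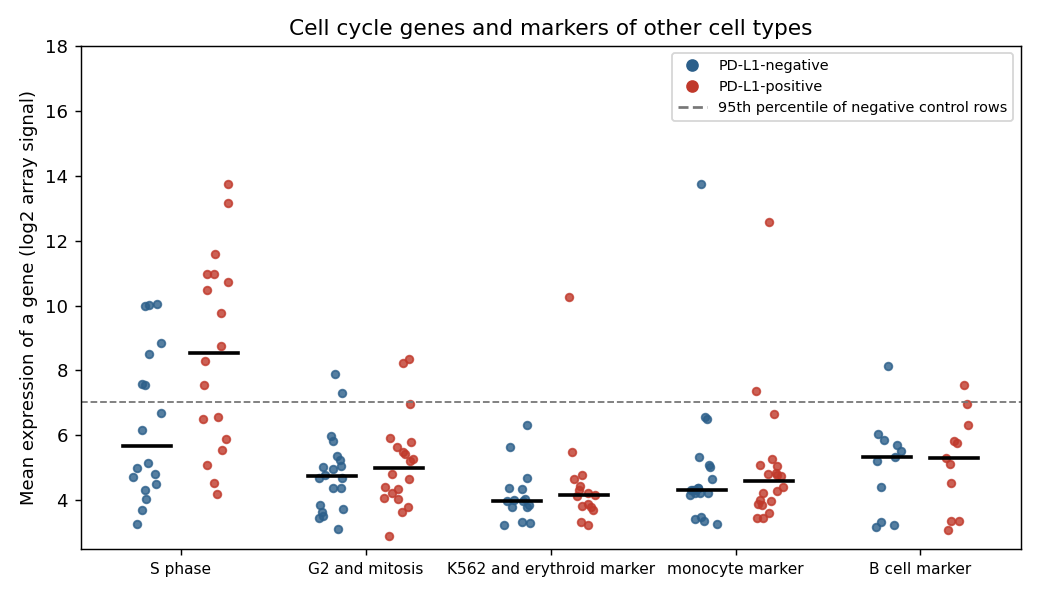
Mean log2 array signal of each measured gene of 5 lists in PD-L1-negative (blue) and PD-L1-positive (red) cells, mean of 3 donors, with a black bar for the median of the genes and a dashed line at 7.02, the 95th percentile of the negative control probes. In S phase 13 genes were called higher, and of the K562 and erythroid markers HBA1 alone lay above the line.

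In all, 14 of 28 lists passed camera with its preset correlation, 8 higher and 6 lower, relative to all other genes; with an estimated correlation 0 passed, with adjusted p of those 14 from 0.284 to 0.589. The directional test fry, which does not compare a list with other genes, called 11, without the NK activating (adjusted p = 0.112), type I interferon (0.215) and interferon-gamma (0.105) lists. Of the called lists, the NK activating (0.0582), IL-2 and STAT5 (0.118) and interferon-gamma (0.0582) lists were not called after a stricter brightness filter or without at least 1 single array, and the costimulation (0.0607) and NF-kB (0.0675) lists were not called among protein-coding genes alone.

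The positive control probes of the array were also brighter in the PD-L1-positive fraction (13.85 ± 0.181 against 13.03 ± 0.0656, exact permutation p = 0.1), while the negative controls stood at 4.52 ± 0.0646 and 4.49 ± 0.043. Centring the arrays on these positive controls, a setting chosen after seeing the data, moved the median of all genes from 0.03 to -0.79 and the split from 2461 higher and 1201 lower to 1057 higher and 12615 lower. Relative to that shift the differences between genes were as given above, but the same shift lowered every list median, to -0.212 for NF-kB and -0.181 for interferon-gamma genes, which says nothing about these lists themselves. The S phase median was 1.31 and stayed called. The calls of STX11, IL2RA, BIRC3, STAT5A, JAK2, IRF8, HMGCS1, CHAC1, BAX, ZMAT3, AURKA, CCNB1 and TBX21 ended, BANK1 changed sign without a call, and the NK activating, inhibitory, type I interferon and homing lists were no longer called (adjusted p = 0.695, 0.113, 0.0738 and 0.0533).

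The calls of CCL1, CCR7, KLF2, CCL5, TNFSF14, BANK1, BAX, ZMAT3, AURKA, CCNB1, TBX21, RICTOR, CHAC1, CXCR2, GPI, OAS1, OSM, CASP8, CD96, IRF8, PFKFB3 and STX11 each ended when at least 1 single array was left out, with adjusted p between 0.0505 and 0.161. Without both arrays of donors 1, 2 and 3, 12, 27 and 34 named genes lost their calls, and 2, 7 and 8 with the donor as a replicate block. Beyond the genes just listed, these were TNFSF4 (adjusted p = 0.0536 without donor 1), SERPINB9, ASNS, LAIR1, ICAM1, BIRC3, STAT5A, IFIT1, IFI27, HMGCS1, CD226, KLRB1, WARS1, JAK2, PFKL, FDPS, ATP5F1B, GATA3 and NCAM1. With the mean of all rows of a gene, CCNG2 was at -2.38, INPP5D at -1.10 and TFRC at 1.87, all still called, and BANK1 at 0.30 was not (adjusted p = 0.444). Apart from the 20 genes with the largest differences, RPTOR, FOSL1, DUSP4, OSM, CHAC1 and MCM5 in PD-L1-negative cells and KLRG1, SESN1, KLF2, LAIR1 and GATA3 in PD-L1-positive cells were under the background level, so the size of their differences is uncertain.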

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

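Of the settings below, centring on the positive controls, protein-coding genes alone and the estimated correlation with the replicate block were chosen after the data were seen. The number of called genes, 3662, was within 1.5 times of that value with the donor as a replicate block (4365, 2843 higher and 1522 lower, 3585 of the 3662 shared), quantile normalization (3691), median centring (3711), trend and robust (3659), mean of rows (3566), no filter (3431), the stricter filter (3751), protein-coding genes (3315), all rows (2904 of 134847, of which 617 of 98008 unnamed rows) and an adjusted p under 0.1 (4829). An unadjusted p under 0.05 with a 1.5-fold difference gave 5651 genes (2049 lower), and with the replicate block 6119 (3857 higher, 2262 lower), by a looser threshold. Centring on the positive controls gave 13672 genes, 1057 higher and 12615 lower, 2258 shared, by the shift it adds to every gene. Leaving out arrays or donors gave 1189 to 3733 genes (785 to 2515 higher, 404 to 1218 lower), and leaving out a donor with the replicate block 2900 to 4629 (at most 3030 higher and 1599 lower). The total was 2329 without the PD-L1-positive array of donor 3, 2428 without its PD-L1-negative array, 1696 without donor 2 and 1189 without donor 3, and 758 genes were lower without the PD-L1-positive array of donor 2. The difference of CD274 lay between 4.74 and 5.93 and passed in every setting.

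Lists called numbered 14 with the replicate block, 10 to 15 in the settings with all samples and a preset correlation, 11 with fry, 12 to 16 without arrays or donors, and 0 with an estimated correlation, without or with the replicate block. By the sign of the list test, uncalled lists that turned direction were cytokines (0.0545 with the replicate block, alone or with the estimated correlation, and in protein-coding genes, by the sign of the test; -0.0259 with the stricter filter), immediate early genes (-0.863 with positive control centring; -0.0443 with fry), CD56-bright markers (-0.981 with that centring; -0.0898 with the stricter filter) and monocyte markers (0.0855 with quantile normalization, 0.0842 without filter, 0.0532 with fry). Without arrays or donors, their medians ran from -0.0193 to 0.195 for cytokines, -0.353 to 0.104 for immediate early genes, -0.528 to 0.133 for CD56-bright, -0.0195 to 0.115 for monocyte and -0.0792 to 0.16 for B cell markers. The median of cytotoxic genes was -0.0632 without the PD-L1-negative array of donor 3. With positive control centring the medians moved by the shift it adds to every gene, and the cause of the turns of the list test was not tested in any setting. Calls were gained by amino acid starvation genes without filter (adjusted p = 0.0464), with positive control centring (0.0498) and in 4 leave-outs, by NK transcription factors with quantile normalization and without donor 1 (0.0468), and by T cell markers in 1 leave-out (0.0482). The IL-2 and STAT5 and interferon-gamma lists also lost their call with quantile normalization (adjusted p = 0.127 and 0.148), as did NF-kB (0.0505).

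Of 111 named genes in 22 settings, 2223 results kept direction and side of the threshold, 184 lost the call, 28 gained it and 6 turned. BANK1 (-0.0423), IFNG (-0.781) and GZMB (-0.0854) turned with positive control centring, and MKI67 with quantile normalization (0.0125) and without single arrays (-0.155 to 0.0742). With the replicate block no named gene lost its call, and XCL1, HBA1, HBA2 and FCGR3A gained one, as did IL3RA and AIF1 outside these 111. A single gene under the background level of 7.02 in both fractions, as most mitosis genes were, was not measured well enough to call it absent or equal.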

Other observations

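The added lists and all tests of explanations below were chosen after the results were seen. Genes counted as not seen before were those outside the earlier lists and outside the 40 largest called rises and the 40 largest called falls. Since the added lists were chosen from these same data, their p-values are no independent support. Genes of ribosome biogenesis rose in PD-L1-positive cells, where 21 of 22 tested genes not seen before were higher, with a median log2 difference of 2.48 (camera adjusted p = 6e-17; adjusted p = 0.119 with an estimated correlation). Of 16 such genes of purine, pyrimidine and folate synthesis, 14 rose with a median of 1.90 (adjusted p = 5.2e-10; adjusted p = 0.119 with an estimated correlation). Of 16 aminoacyl-tRNA synthetases, which charge tRNAs for translation, 10 rose with a median of 1.20 (adjusted p = 1.2e-06; adjusted p = 0.119 with an estimated correlation). TFRC, the transferrin receptor, rose by 3.71 (SE 0.44) and IRF4, a transcription factor of activated lymphocytes, by 4.58 (SE 0.40).

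The list of genes linked to quiescence and FOXO factors was called lower at the preset correlation. Of 7 tested that had not been seen before, 4 fell and 3 were not past the test, with a median of -1.35 (adjusted p = 0.000225; adjusted p = 0.119 with an estimated correlation). The cyclin-dependent kinase inhibitor gene CDKN1B (-2.95), S1PR1 (-3.19) and PIK3IP1 (-2.37) fell beside YPEL3, MXI1 and CCNG2 (PIK3IP1 to 6.13, under background), whereas TXNIP (-0.17), IL7R (-0.30) and BCL6 (0.67, higher in all 3 donors) of the same list were not called. Of an added list of 8 red cell genes, 1 was tested, HBB (0.13), and 0 were called.

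Of the 10 splits of the 6 samples into 3 and 3, 1 called as many genes as the sorted fractions, the real split with 3662, and the highest of the others called 0. So few splits cannot give a share under 0.05.

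S phase and activation genes were higher in the PD-L1-positive fraction, which could reflect RNA of other cells. K562 cells divide and would bring their own transcripts, but 14 K562 and erythroid markers without HBA1, none above background in either fraction, had a mean median difference of 0.106 (SD 0.075 over 3 donors) and mitosis genes one of 0.301 (SD 0.255), against 2.16 (SD 0.655) for S phase genes. HBA1 was higher, but by 6.66, 4.01 and 1.15 in donors 1, 2 and 3, where the S phase list had 1.45, 2.30 and 2.74, and HBG1 and HBG2, globins of K562, had no value. Monocytes or B cells would bring CD83 and CCR7, but 31 of their markers had 0.049 (SD 0.0802), against 4.49 (SD 0.353) for CD83, CCR7, TNFSF4 and LTA. Of these 31, CD68, AIF1 and CD79B alone were above background in the PD-L1-positive fraction. CD68 (-1.17) and CD79B (-0.61), above background, lay lower in all 3 donors, although AIF1 (0.80), MZB1 (0.94) and BANK1 (0.78) lay higher. No sample here shows that the probes of markers under background respond to such cells. If they do, these differences argue against monocytes, B cells and, for the S phase difference, K562 as the main source. The gate after culture was set to exclude these cells, with a sort purity of at least 96%, which does not show that none were left. Dendritic cells stay open, although the gate applied to them too, since of 10 measured markers only 2 were above background, LAMP3 (-0.08) and IL3RA (2.00). A start of DNA replication ahead of mitosis stays open: the gap between the lists, 1.86, restates the pattern, and mitosis genes were under background.

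The CD56-dim list was called lower in PD-L1-positive cells, for which a larger share of CD56-bright cells is a candidate explanation. Of 9 CD56-bright markers, 3 were higher in all 3 donors, whereas XCL1 (-2.72), KLRC1 (-0.43) and CAPG (-0.56, under background) were lower in all 3. NCAM1, the gene of CD56, was also lower (-2.01, and -1.27 without a call with the mean of its rows). FCGR3A (-0.92, 95% interval -2.42 to 0.58; -1.49 to -0.344 with the donor as a replicate block, where it was called) and PRF1 (-0.23, interval -0.82 to 0.36) lay above FGFBP2 (-5.93, interval -7.63 to -4.22). Each marker would move by its own ratio between the subsets, which no table gives, and PRF1 was at 18.4 and 18.6, near the top of the scale. Composition and a change of expression within cells both stay open.

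HBA1 and HBA2, whose differences were equal within 2e-05 and count as 1 measurement, were higher by 6.66, 4.01 and 1.15 in donors 1, 2 and 3, with HBA1 at 14.5 in the highest sample. Red cell or K562 RNA could bring them, but 22 other red cell and K562 genes had a mean median difference of 0.129 (SD 0.0916), and none was above background (highest 5.47). HBG1 and HBG2, globins of K562, lay on rows naming several genes and had no value. If their probes respond to such RNA, which no sample here shows, the measured genes argue against red cells and less firmly against K562. The cause stays open.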
